A study of Drosophila melanogaster with 43 samples.

How the data were processed

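Of 43 samples in the series, 16 libraries were analysed here: 4 of S2 cells (2 background, 2 Orb2B) and 12 of head b-isox fractions (6 pellet, 6 supernatant). The crosslinking libraries of Orb and Orb2B were not analysed here. Per the labels, both S2 groups received 250 µM copper sulfate, and the Orb2B cells alone received 300 µg/ml hygromycin B. The labels do not state that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

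For the S2 libraries the authors deposited RPKM per gene. Of the identifiers, 12895 matched the reference name table. The submitters' processing notes name CASAVA 1.9.1, Bowtie, cutadapt and Novoalign without saying which step each served. For the heads the authors deposited FPKM per gene or assembled locus, and the notes name CASAVA 1.9.1, TopHat and Cufflinks. The notes give genome build dm3. Head replicates 1 to 4 carried gene names. Replicates 5 and 6 held assembled loci without names, so a fit over 6 replicates with the library series as a covariate, intended before the data were examined, was made over replicates 1 to 4, which belong to 1 series. Some head entries carried a FlyBase identifier and others an identifier of assembled transcripts, and some joined several genes. Genes joined in any library were merged. This gave 14447 features, of which 14410 had a value in all 8 libraries and 949 of these held several genes. Entries without a gene name were left out. They held 22.3% to 97.2% of the summed FPKM of a library, and in each library most of that lay in very short entries. FPKM is given per kilobase, so these are not shares of reads.

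Each library was divided by the median over genes of its ratio to the gene's geometric mean. In the heads these factors were 0.665 to 0.737 for supernatants and 1.27 to 1.65 for pellets. Genes with a mean of at least 1 were tested with limma 3.58.1 in R 4.3.3 on log2(scaled value + 0.5), with a mean-variance trend and two-sided. An adjusted p (Benjamini-Hochberg) under 0.05 was called a change. Fold changes on this scale understate the change of low genes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. The 33 gene lists, these tests, the rule for named genes and most alternatives were fixed before the data were examined. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

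The named genes were orb2 and orb, then the 10 largest increases and 10 largest decreases among called genes with a scaled mean of at least 5 in the higher group. These had to move the same way in every pair of head libraries, or not overlap between the S2 groups. From each list that passed, the up to 4 members with the smallest p were named, or the 2 with the highest mean where no member passed. Of the genes this rule takes, 1 is not reported here. Pellet and supernatant libraries of the same number deviated together (correlations across genes of 0.166, 0.191, 0.326 and 0.196 for replicates 1 to 4). The highest correlation with a library of another number was 0.143, 0.113, 0.0398 and -0.0542, close to the first for replicates 1 and 2. Since each pair exceeded 0.1, the numbers were taken to pair the head libraries, from the data alone, as the labels do not say what a number marks. For replicates 1 and 2 a library of another number exceeded 0.1 too, so the pairing is uncertain there. Values with the replicate as a block stand beside the results and rest on this pairing. Alternatives were pseudocounts of 0.1 and 1, no filter and a minimum of 5, values as deposited, quantile normalization, the replicate block, no variance trend, a log2 change of at least 1, and each replicate left out. Further alternatives were added after seeing the data: exact 0 as missing, features with FlyBase entries, features of 1 gene, and replicates 5 and 6 joined by at least 50% reciprocal overlap of loci.

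The procedure was tested on simulated data with 200 changed genes. In the S2 design, with each gene's own moderated variance, 88 of 98 genes changed by a log2 of 1 and 98 of 98 changed by 2 were recovered, and 13.4% of calls were unchanged genes. With variances drawn from the fitted prior, 34 of 97 and 98 of 100 were recovered, with 5.23% of calls unchanged genes. In the head design 22 of 99 and 74 of 100 were recovered with each gene's own variance, and 3.77% of calls were unchanged genes. With the prior variance these were 25 of 96, 69 of 100 and 7.34%.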

Results

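Messenger RNA was measured in S2 cells, a cultured Drosophila line with features of blood cells, and in fly heads fractionated with biotinylated isoxazole (b-isox). This compound precipitates proteins with low-complexity domains together with RNA. The series concerns Orb and Orb2, the fly CPEB proteins, which bind mRNA and control its translation. The S2 part held 2 libraries of background cells and 2 of cells that carried Orb2B, a form of Orb2. The head part held 6 pellet and 6 supernatant libraries. The S2 libraries had 6670 to 7129 genes at 1 RPKM or more. The sequencing depth is unknown, so no counting interval is given. Values are means ± SD, with n = 2 per S2 group and n = 4 per head fraction.

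The first comparison asked how the mRNA of S2 cells that carried Orb2B differed from that of background cells. The orb2 transcript, which checks the labels, was at 7.5 and 8.73 RPKM in the background libraries and at 2509 and 2850 RPKM in the Orb2B libraries (log2 fold change 8.34, SE 0.16, limma adjusted p = 5.11e-07). Glycolytic enzymes and respiratory chain genes were higher as groups in Orb2B cells, and immune-induced genes and detoxification enzymes were lower. These group calls were lost in camera with an estimated correlation, where 0 of the 18 S2 lists passed (smallest adjusted p = 0.624). That test takes its degrees of freedom from the few libraries, so the loss cannot show that correlated genes made the calls. The detoxification list lost its call at an estimated correlation of -0.0134, below the preset of 0.01. The other called lists had estimates above the preset. These were 0.735 for glycolysis, 0.497 for mitochondrial ribosomal, 0.368 for immune-induced and 0.301 for respiratory chain genes. Cell-division genes had 0.277, chaperones 0.189 and blood-cell markers 0.0401. For these lists correlated members may have made part of the calls, which stay uncertain. Of 7072 genes tested, 1201 were higher and 1410 were lower. Without Orb2B replicate 1 the total of 2611 became 1255, and without Orb2B replicate 2 it became 1729. The orb gene was below the minimum for a test, at 0.141 and 0.166 RPKM in background and 0.0774 and 0.06 RPKM in Orb2B cells.

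Among the genes with the largest increases, argos, a secreted inhibitor of the epidermal growth factor receptor, was at 5.37 ± 1.83 RPKM in background and 264 ± 15 RPKM in Orb2B cells (log2 fold change 5.58, SE 0.21). The kinase gene Pka-C3 was at 1.22 ± 0.106 RPKM in background and 65.8 ± 8.21 RPKM in Orb2B cells (log2 fold change 5.31, SE 0.22). The homeobox gene btn was at 17 ± 5.06 RPKM in background and 366 ± 32 RPKM in Orb2B cells, and twi, a transcription factor of the mesoderm, was at 11.8 ± 3.3 RPKM in background and 225 ± 21.5 RPKM in Orb2B cells. Their log2 fold changes were 4.48 and 4.28. The perlecan gene trol rose by 4.05 and kirre, an adhesion protein of myoblasts, rose by 3.94 on the log2 scale. CG42857 and CG30089 rose by 5.55 and 5.04. CG14397 was listed at 0 in both background libraries and at 10.5 and 11.1 RPKM in the Orb2B libraries. The limma adjusted p of these genes lay between 1.11e-05 and 7.76e-05.

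TotM, a secreted stress-response protein, had the largest decrease, with 404 and 357 RPKM in background cells and 0 and 0.261 RPKM in Orb2B cells. CG13559 was at 134 ± 5.76 RPKM in background and 0.611 ± 0.615 RPKM in Orb2B cells (log2 fold change -7.01, SE 0.35). CG14419 and CG4250 had log2 fold changes of -6.96 and -6.18. The serpin gene Spn88Eb was at 44.9 ± 4.68 RPKM in background and 0.0376 ± 0.0532 RPKM in Orb2B cells (log2 fold change -6.37, SE 0.23). CG33462, CG42566 and Msr-110 had log2 fold changes of -5.87, -5.83 and -5.68. Ama, an adhesion protein with immunoglobulin domains, was at 168 and 189 RPKM in background and 0.533 and 8.11 RPKM in Orb2B cells. The odorant-binding protein gene Obp99c was at 231 and 179 RPKM in background and 0.525 and 21 RPKM in Orb2B cells. Without Orb2B replicate 1 the log2 fold changes of Ama, Obp99c and CG4250 were -4.37, -3.24 and -5.53, and without Orb2B replicate 2 they were -7.33, -7.53 and -6.80. For these genes the limma adjusted p lay between 2.53e-06 and 0.00865.

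**Figure D1:**
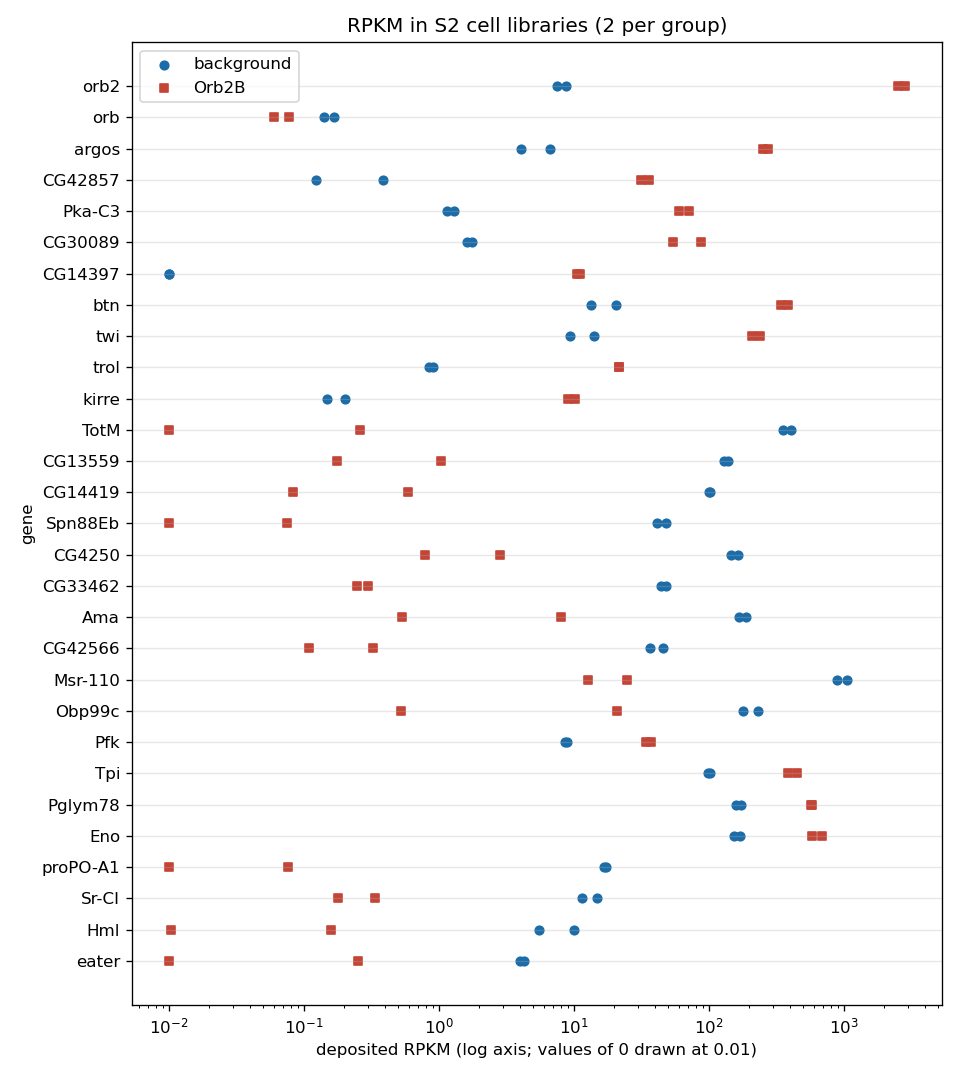
Deposited RPKM (log axis, values of 0 drawn at 0.01) of named genes in the 2 background (circles) and 2 Orb2B (squares) S2 libraries, with a point per library. The orb2 points lie at 7.5 and 8.73 RPKM in background and 2509 and 2850 RPKM in Orb2B cells.

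Of 12 glycolytic enzymes, 11 rose and 1 did not pass, and 12 rose adjusted over the list alone. The glycolysis list had a median log2 difference of 1.68, with camera adjusted p = 9.39e-07 and adjusted p = 0.78 with an estimated correlation. The phosphofructokinase gene Pfk was at 8.74 ± 0.145 RPKM in background and 35.8 ± 2.51 RPKM in Orb2B cells. The triose phosphate isomerase gene Tpi rose by 2.11, Pglym78 by 1.84 and the enolase gene Eno by 2.02 on the log2 scale. Of 24 nuclear-encoded respiratory chain genes, 12 rose, 2 fell and 10 did not pass, and 15 rose and 2 fell adjusted over the list alone. The respiratory chain list had a median log2 difference of 0.60, with camera adjusted p = 0.00226 and adjusted p = 0.78 with an estimated correlation. RFeSP, the Rieske iron-sulfur protein, rose by 1.62, the ATP synthase subunit gene Oscp by 1.18 and CG4769 by 0.92, while ox had a log2 fold change of -1.17. Of 72 mitochondrial ribosomal protein genes, 23 rose, 6 fell and 43 did not pass, and 24 rose and 7 fell adjusted over the list alone. The mitochondrial ribosomal list had a median log2 difference of 0.42, with camera adjusted p = 0.00351 and adjusted p = 0.821 with an estimated correlation. Against the list's direction, mRpL34, mRpL23 and mRpL32 fell, with log2 fold changes of -3.15, -1.57 and -2.56, and mRpL14 rose by 1.01. The call ended with quantile normalization (adjusted p = 0.0909) and without background replicate 2 (adjusted p = 0.154). Of 14 heat shock and chaperone genes, 5 rose and 9 did not pass, and 3 rose adjusted over the list alone. The chaperone list had a median log2 difference of 0.51, with camera adjusted p = 0.0211 and adjusted p = 0.78 with an estimated correlation. The small heat shock protein gene Hsp26 was at 24.9 ± 5.12 RPKM in background and 141 ± 80.4 RPKM in Orb2B cells. Hsp23, Hsp22 and stv rose by 1.96, 1.72 and 1.02, and each lost its call under some settings. Without Orb2B replicate 1 the log2 fold changes of Hsp26, Hsp23 and Hsp22 were 1.76, 1.21 and 0.78, and without replicate 2 they were 3.13, 2.74 and 2.69. The chaperone call ended with quantile normalization (adjusted p = 0.0909) and without background replicate 1 (adjusted p = 0.0753).

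Of 21 antimicrobial and immune-induced genes, 3 rose, 14 fell and 4 did not pass, and 3 rose and 14 fell adjusted over the list alone. The immune list had a median log2 difference of -1.49, with camera adjusted p = 0.000381 and adjusted p = 0.78 with an estimated correlation. TotM was a member. The antimicrobial peptide gene DptB was at 93.6 ± 11.6 RPKM in background and 9.79 ± 1.58 RPKM in Orb2B cells. Dro, which encodes another such peptide, and the Toll ligand gene spz had log2 fold changes of -3.14 and -3.14, and that of spz was -2.50 and -3.74 without Orb2B replicate 1 and 2. Of 32 detoxification enzymes, 2 rose, 18 fell and 12 did not pass, and 3 rose and 20 fell adjusted over the list alone. The detoxification list had a median log2 difference of -1.06, with camera adjusted p = 4.38e-05 and adjusted p = 0.624 with an estimated correlation. The glutathione transferase gene GstD7 was at 74.2 ± 4.02 RPKM in background and 11.2 ± 2.01 RPKM in Orb2B cells. GstE6, GstE3 and the cytochrome P450 gene Cyp6a23 had log2 fold changes of -2.53, -2.51 and -2.52.

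Of 18 blood-cell markers, 2 rose, 7 fell and 9 did not pass, and 2 rose and 7 fell adjusted over the list alone. The blood-cell list had a median log2 difference of -0.47, with camera adjusted p = 0.0317 and adjusted p = 0.78 with an estimated correlation. The prophenoloxidase gene proPO-A1 was at 17.1 ± 0.416 RPKM in background and 0.0385 ± 0.0544 RPKM in Orb2B cells. The scavenger receptor gene Sr-CI, the clotting gene Hml and the phagocytic receptor gene eater had log2 fold changes of -4.13, -3.75 and -2.90. The blood-cell call ended with a minimum mean of 5 (adjusted p = 0.0657), without background replicate 1 (adjusted p = 0.074) and without background replicate 2 (adjusted p = 0.0519). Of 41 replication and cell-division genes, 1 rose, 9 fell and 31 did not pass, and 4 fell adjusted over the list alone. The cell-division list had a median log2 difference of -0.38, with camera adjusted p = 0.0317 and adjusted p = 0.821 with an estimated correlation. The mitotic kinase gene aur, the cyclin-dependent kinase genes cdc2c and cdc2, and Mcm7, of the replicative helicase, had log2 fold changes of -1.43, -2.20, -1.68 and -1.28. The cell-division call ended without background replicate 2 (adjusted p = 0.0583) and without Orb2B replicate 1 (adjusted p = 0.37).

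The other S2 lists had camera adjusted p of 0.133 or more. The unfolded protein response list had 22 tested, 1 rose and 5 fell, 4 fell adjusted over the list alone, with a median of -0.33. RNA granule and translational control genes had 33 tested, 8 rose and 4 fell, 8 rose and 4 fell adjusted over the list alone, with a median of 0.21. Germline genes had 13 tested, 1 rose and 5 fell, 2 rose and 6 fell adjusted over the list alone, with a median of -0.46. Cytoplasmic ribosomal protein genes had 82 tested, 1 rose and 9 fell, 4 fell adjusted over the list alone, with a median of -0.18. Proteasome genes had 29 tested, 1 rose and 5 fell, 1 rose and 4 fell adjusted over the list alone, with a median of -0.19. Metal response genes had 16 tested, 2 rose and 3 fell, 2 rose and 3 fell adjusted over the list alone, with a median of -0.45. Ecdysone response genes had 12 tested, 3 rose and 5 fell, 3 rose and 5 fell adjusted over the list alone, with a median of -0.45. Translation factors had 31 tested, 5 rose and 4 fell, 3 rose and 4 fell adjusted over the list alone, with a median of -0.04. Proton pump genes had 20 tested, 1 rose and 2 fell, 2 fell adjusted over the list alone, with a median of -0.07. Histone genes had 5 tested, 2 fell, 2 fell adjusted over the list alone, with a median of 0.00. The histone mean was -0.32, while its median of 0.00443 had the other sign, and the histone median was -0.05 with values as deposited. Mitochondrially encoded transcripts were listed at 0 and not tested. On simulated data of this design, 13.4% or 5.23% of calls were unchanged genes, depending on how variances were drawn. The simulation changed far fewer genes than the 2611 called here, so these shares do not carry over to those calls. Hygromycin B was given to the Orb2B cells only, and the background cells were not transfected, so the antibiotic and the transfection differed together with Orb2B in every library.

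The second comparison asked which mRNAs of fly heads were more abundant in the b-isox pellet than in the supernatant. Ribosomal protein genes and translation factors were lower as groups in the pellet relative to the median gene, and genes of RNA granules and ion channels were higher. All group calls were lost in camera with an estimated correlation, where 0 of the 29 head lists passed (smallest adjusted p = 0.19). Here too the degrees of freedom come from few libraries, so this loss alone does not decide the calls. Estimated correlations were 0.348 for ribosomal proteins, 0.302 for ion channels, 0.0631 for translation factors and 0.0319 for RNA granule genes, above the preset of 0.01. Correlated members may therefore have made part of the calls. At least 14 lists, the number called here, also passed in 11 of 35 splits of the 8 libraries, the real one included. Gene names were present in replicates 1 to 4, which form the comparison. Of 8720 features tested, 172 were higher and 154 lower in the pellet, and 609 and 659 with the replicate as a block. Deposited FPKM was higher in the pellets by a median log2 difference of 0.87, and the directions given here are relative to that shift. With values as deposited 4526 features were higher and 40 lower. The total of 326 became 66, 77, 209 and 87 without replicate 1, 2, 3 and 4. Of 41 called features among those chosen to be named, 15 kept the call with each replicate left out in turn.

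The orb2 gene shared a feature with CG43783 (dm3 chromosome 3L, 8925334 to 8947563). It was at 24.1 ± 5.44 scaled FPKM in the supernatant and 41.6 ± 10.7 in the pellet (log2 difference 0.77, SE 0.25). This difference did not pass without the pairs (limma adjusted p = 0.131) and passed with the replicate block (adjusted p = 0.0192). The orb gene (chromosome 3R, 19090363 to 19106571) was at 2.25 ± 0.989 scaled FPKM in the supernatant and 2.7 ± 0.895 in the pellet and passed in neither fit (adjusted p = 0.666, and 0.505 with the block).

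Among the features with the largest pellet increases, Nf1, the neurofibromin gene whose product restrains Ras, was at 4.02 ± 3.5 scaled FPKM in the supernatant and 32.8 ± 24.1 in the pellet (log2 difference 2.99, SE 0.66). The laminin gene wb was at 1.78 ± 2.54 scaled FPKM in the supernatant and 11.2 ± 2.33 in the pellet, and tara was at 7.04 ± 1.23 scaled FPKM in the supernatant and 66.3 ± 35.1 in the pellet. The gene nej, which encodes a histone acetyltransferase, was at 23 ± 6.95 scaled FPKM in the supernatant and 165 ± 121 in the pellet (log2 difference 2.58, SE 0.51). Its adjusted p of 0.0339 became 0.0511 with the replicate block. CG14693, CG12290, CG32773 and CG11873 rose by 2.71, 2.42, 3.45 and 2.87 on the log2 scale. CG8468 was listed at 0 in all 4 supernatants and at 3.38, 3.53, 28.8 and 23.6 FPKM in the pellets. CG2909 was at 2.06, 0, 0 and 0 FPKM in the supernatants and at 34.3, 22.2, 17.4 and 31.7 FPKM in the pellets. Without replicate 4 the log2 difference of CG11873 was 3.56, and without replicate 1 that of nej was 1.91. These features had limma adjusted p between 0.000748 and 0.0487, and among them CG12290 alone kept its call with each replicate left out in turn. Nf1, CG11873, CG8468, CG32773 and wb also lost the call under other pseudocounts, scalings, filters or variance settings.

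On the lower side, Arc1, whose product forms capsid-like particles, shared a feature with CR10102 and was at 1927 ± 394 scaled FPKM in the supernatant and 265 ± 93 in the pellet (log2 difference -2.90, SE 0.27). The copies 7SLRNA:CR32864 and 7SLRNA:CR42652 of the signal recognition particle RNA each had a log2 difference of -2.87, and as near-identical copies they share reads. The receptor gene Ir76a was at 18.7 ± 6.39 scaled FPKM in the supernatant and 2.32 ± 0.606 in the pellet. CG2182, CG32444 and the feature of CG33509 with the ion channel gene ppk13 had log2 differences of -2.37, -1.82 and -2.78. The augmin subunit gene dgt4, the ubiquitin ligase gene Cbl and CG10462 were listed at 0 in all 4 pellets. In supernatants 1 to 4 dgt4 was at 71.7, 66.9, 39.6 and 34.2 FPKM and Cbl at 12.8, 12.2, 12.6 and 10.7 FPKM. CG10462 was at 7.8, 2.34, 2.31 and 2.6 FPKM there. An exact 0 can be a failed estimate in these files, since the glycolytic enzyme gene Pgk, chosen after its values were seen, was listed at 0 in pellets 3 and 4 and at 174 and 178 FPKM in pellets 1 and 2. Limma adjusted p on this side lay between 6.11e-06 and 0.0072.

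Of 84 cytoplasmic ribosomal protein features, 58 fell and 26 did not pass, and 75 fell adjusted over the list alone. The ribosomal protein list had a median log2 difference of -1.01 (-0.01 with values as deposited, -0.41 with quantile normalization), with camera adjusted p = 7.06e-50 and adjusted p = 0.19 with an estimated correlation, and 74 fell with the replicate block. RpS13 was at 6261 ± 277 scaled FPKM in the supernatant and 2597 ± 113 in the pellet. RpS26 and the feature of RpL28 with its snoRNAs had log2 differences of -1.40 and -1.65. Of 32 translation factor features, 9 fell and 23 did not pass, and 2 rose and 14 fell adjusted over the list alone. The translation factor list had a median log2 difference of -0.47 (0.44 with values as deposited), with camera adjusted p = 1.91e-05 and adjusted p = 0.211 with an estimated correlation, and 2 rose and 15 fell with the replicate block. Ef1gamma, of the elongation factor, was at 679.6 ± 58.7 scaled FPKM in the supernatant and 233 ± 47.1 in the pellet. The helicase gene eIF-4a, Ef1beta and eIF2B-gamma had log2 differences of -1.34, -1.33 and -0.86. In a refit to features with FlyBase entries in all 8 libraries, added after seeing the data, the translation factor call ended (camera adjusted p = 0.541, 5 members). In the fit to all features these 5 members had a median of -0.49, near that of the 32 members. With values as deposited RpS13, RpS26, eIF-4a and Ef1beta lost their calls, and with quantile normalization the RpL28 feature did.

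Of 71 mitochondrial ribosomal protein features, 1 fell and 70 did not pass, and 1 fell adjusted over the list alone. The mitochondrial ribosomal list had a median log2 difference of -0.36 (0.64 with values as deposited), with camera adjusted p = 9.82e-06 and adjusted p = 0.495 with an estimated correlation, and 15 fell with the replicate block. The member that fell was mRpS22 (log2 difference -0.80, SE 0.14), and mRpS35, mRpL44 and mRpL40 had -0.63, -0.75 and -0.66 and passed with the block alone (adjusted p = 0.0397, 0.0396 and 0.0248). Of 28 respiratory chain features, 3 fell and 25 did not pass, and 9 fell adjusted over the list alone. The respiratory list had a median log2 difference of -0.39 (0.61 with values as deposited), with camera adjusted p = 0.000185 and adjusted p = 0.421 with an estimated correlation, and 10 fell with the replicate block. The log2 differences were -0.85 for levy, -0.76 for ATPsyn-d, -0.66 for ATPsyn-gamma and -0.70 for Pdsw, of which Pdsw passed with the block alone (adjusted p = 0.0219). With quantile normalization levy had -0.38 and lost its call (adjusted p = 0.148). ATPsyn-gamma lost its call without the variance trend (adjusted p = 0.0553) and among FlyBase entries (adjusted p = 0.0513). Of 28 proteasome features, 28 did not pass, and 1 rose and 4 fell adjusted over the list alone. The proteasome list had a median log2 difference of -0.42 (0.57 with values as deposited), with camera adjusted p = 9.43e-05 and adjusted p = 0.437 with an estimated correlation, and 1 rose and 9 fell with the replicate block. Prosalpha7 had -0.77 and passed with the block alone (adjusted p = 0.0257), and the feature of Rpn12 with CG4169 had -0.07, with pellet 4 at 13240 scaled FPKM against 436 to 716 in the other pellets. Without replicate 4 this feature had -1.05, and without replicate 1, 2 or 3 it had 0.34, 0.27 and 0.19. Of 92 histone features, 92 did not pass, and 0 changed adjusted over the list alone. The histone list had a median log2 difference of -0.80 (0.19 with values as deposited), with camera adjusted p = 2.33e-10 and adjusted p = 0.421 with an estimated correlation, and 46 fell with the replicate block. With values as deposited the calls of the mitochondrial ribosomal (adjusted p = 0.0867), respiratory (adjusted p = 0.994) and proteasome lists (adjusted p = 0.285) ended. In the refit to features with FlyBase entries in all 8 libraries the proteasome call also ended (camera adjusted p = 0.647, 5 members). In the fit to all features these 5 members had a median of -0.41. Most histone features are near-identical repeat copies that share reads. His3.3B and His4r, the members with the highest means, had -0.33 and 0.32.

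Of 42 RNA granule and translational control features, 6 rose and 36 did not pass, and 9 rose adjusted over the list alone. The RNA granule list had a median log2 difference of 0.44, with camera adjusted p = 3.14e-05 and adjusted p = 0.19 with an estimated correlation, and 13 rose and 1 fell with the replicate block. The deadenylase scaffold gene Not1 was at 69.5 ± 9.04 scaled FPKM in the supernatant and 222 ± 83.5 in the pellet, and the translational repressor gene pum was at 169.9 ± 31.8 scaled FPKM in the supernatant and 436 ± 102 in the pellet. The RNA-binding protein gene elav and brat rose by 1.02 and 1.13 on the log2 scale. Of 27 ion channel features, 1 rose and 26 did not pass, and 11 rose adjusted over the list alone. The ion channel list had a median log2 difference of 0.98, with camera adjusted p = 2.88e-05 and adjusted p = 0.421 with an estimated correlation, and 9 rose with the replicate block. The potassium channel gene slo rose by 1.58. The sodium channel gene para, Ih and Shawl had 1.10, 1.28 and 1.42, of which para and Ih passed with the block alone (adjusted p = 0.0207 and 0.0206) and Shawl in neither fit. Of 35 adhesion and axon guidance features, 2 rose and 33 did not pass, and 10 rose adjusted over the list alone. The adhesion list had a median log2 difference of 0.69, with camera adjusted p = 3.51e-06 and adjusted p = 0.421 with an estimated correlation, and 8 rose with the replicate block. Ptp99A and side rose by 1.98 and 1.39, and side lost its call with no filter, with quantile normalization and without the variance trend, while hbs and Dscam3 had 0.75 and 1.71, of which hbs passed with the block alone (adjusted p = 0.0332). Of 27 learning and memory features, 2 rose and 25 did not pass, and 5 rose adjusted over the list alone. The memory list had a median log2 difference of 0.64, with camera adjusted p = 3.51e-06 and adjusted p = 0.421 with an estimated correlation, and 9 rose with the replicate block. The members that rose were pum and Nf1, and ben and klg had 1.25 and 1.49, of which klg passed with the block alone (adjusted p = 0.0321).

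Of 34 synaptic features, 1 rose and 33 did not pass, and 6 rose adjusted over the list alone. The synaptic list had a median log2 difference of 0.58, with camera adjusted p = 0.000131 and adjusted p = 0.421 with an estimated correlation, and 5 rose with the replicate block. The vesicle calcium sensor gene Syt1 rose by 1.78, and Rim, the feature of Eps-15 with CG16936 and the feature of Cha, VAChT and CG14302 had 1.34, 0.53 and 1.48. With the block Rim and the Eps-15 feature passed (adjusted p = 0.0155 and 0.0396). Of 30 neurotransmitter receptor features, 30 did not pass, and 0 changed adjusted over the list alone. The receptor list had a median log2 difference of 0.53, with camera adjusted p = 0.00906 and adjusted p = 0.496 with an estimated correlation, and 4 rose and 1 fell with the replicate block. The GABA receptor gene Rdl had 0.72 and nAcRbeta-64B had 0.18. The receptor call ended with a minimum mean of 5 (adjusted p = 0.0506), without replicate 1 (adjusted p = 0.0523) and with values as deposited (adjusted p = 0.992). Of 16 glial markers, 16 did not pass, and 0 changed adjusted over the list alone. The glial list had a median log2 difference of 0.47, with camera adjusted p = 0.00441 and adjusted p = 0.421 with an estimated correlation, and 1 rose with the replicate block. The glutamine synthetase gene Gs2 had 0.86 and e had 1.69, of which Gs2 passed with the block alone (adjusted p = 0.0322). The value of e depended on pellet 2, at 663 scaled FPKM against 35 to 83.4 in the other pellets, and without replicate 2 it was 0.71. With a minimum mean of 5 the glial call ended (adjusted p = 0.0506), as it did with values as deposited (adjusted p = 0.0783). Of 14 clock features, 1 rose and 13 did not pass, and 1 rose adjusted over the list alone. The clock list had a median log2 difference of 0.43, with camera adjusted p = 0.0148 and adjusted p = 0.421 with an estimated correlation, and 2 rose with the replicate block. The transcription factor gene Pdp1 rose by 1.28 but lost its call with no filter, without the variance trend, with a pseudocount of 1 and among features of 1 gene, and sgg, tim and tws had 0.78, 1.46 and 0.70, of which tws passed with the block alone (adjusted p = 0.0491).

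**Figure D2:**
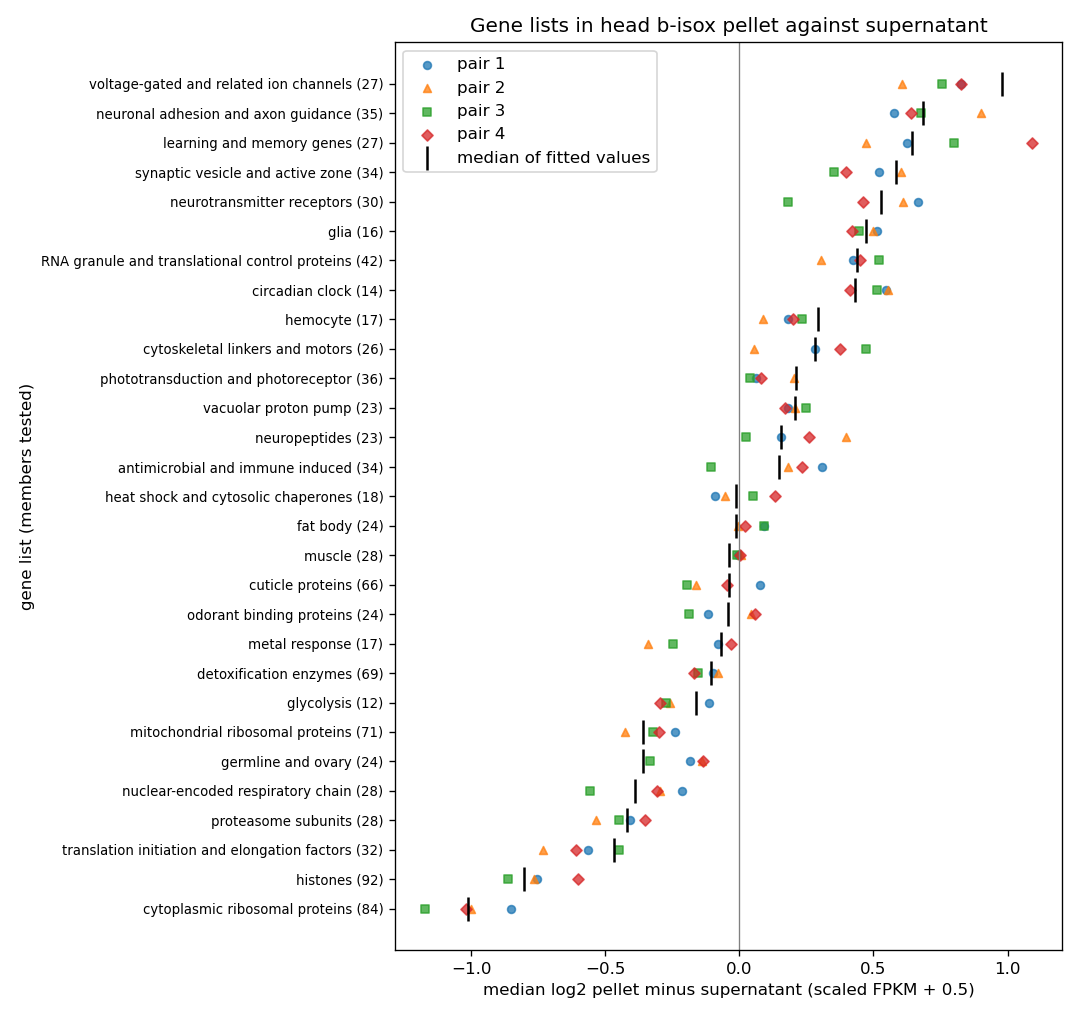
Median log2 pellet minus supernatant difference (scaled FPKM + 0.5) of each gene list in each of the 4 pairs (symbols), with the median of the fitted values as a bar and the members tested in parentheses. The ribosomal protein list lies between -1.17 and -0.85 in the 4 pairs, and its fitted median is -0.01 with values as deposited.

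The other head lists had camera adjusted p of 0.0754 or more, and their medians were above 0 with values as deposited. The proton pump list had 23 tested, 2 rose, 2 rose adjusted over the list alone, with a median of 0.21. Cytoskeletal linkers and motors had 26 tested, 1 rose, 1 rose adjusted over the list alone, with a median of 0.28. Detoxification enzymes had 69 tested, 2 fell, 0 changed adjusted over the list alone, with a median of -0.10. Blood-cell markers had 17 tested, 0 changed, 1 rose adjusted over the list alone, with a median of 0.29. Glycolytic enzymes had 12 tested, 1 fell, 1 fell adjusted over the list alone, with a median of -0.16. The metal response list had 17 tested, 0 changed, 0 changed adjusted over the list alone, with a median of -0.07. Phototransduction genes had 36 tested, 1 fell, 2 rose and 2 fell adjusted over the list alone, with a median of 0.21. Neuropeptides had 23 tested, 0 changed, 0 changed adjusted over the list alone, with a median of 0.15. Immune-induced genes had 34 tested, 0 changed, 0 changed adjusted over the list alone, with a median of 0.15. Cuticle proteins had 66 tested, 2 fell, 2 fell adjusted over the list alone, with a median of -0.04. The germline list had 24 tested, 0 changed, 0 changed adjusted over the list alone, with a median of -0.36. Odorant-binding proteins had 24 tested, 2 fell, 2 fell adjusted over the list alone, with a median of -0.04. Muscle markers had 28 tested, 0 changed, 0 changed adjusted over the list alone, with a median of -0.04. Fat body markers had 24 tested, 1 fell, 1 fell adjusted over the list alone, with a median of -0.01. Chaperones had 18 tested, 0 changed, 0 changed adjusted over the list alone, with a median of -0.01. The means for muscle and fat body were 0.06 and 0.07, of the other sign than their medians. Mitochondrially encoded transcripts were listed at 0 and not tested. In 11 of the 35 splits of the 8 libraries into groups of 4, the real one included, at least 14 lists passed.

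The pellet minus supernatant differences of single pairs were weakly alike. Across genes, which are not independent replicates, Pearson's r between pairs 1 to 4 ranged from 0.23 to 0.309 with a median of 0.252. Replicates 5 and 6 were joined by locus, a choice made after seeing the data. Their differences correlated with those of pairs 1 to 4 at 0.163 to 0.273, and with each other at 0.527. Across 7878 features of 1 gene, the difference correlated with the genomic span of the locus (Spearman's rho 0.356, and 0.284 to 0.367 in single pairs). This relation was chosen after seeing the data in place of transcript length, which was not used here. In 1837 features whose rows carried a FlyBase identifier in all 8 libraries, rho was 0.0205. Their median span was 1264 bp, against 3333 bp for the other tested features, so this loss does not separate span from assembly.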

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

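The tests of assembled isoforms, of background RNA in Orb2B replicate 2 and of single lists across splits were chosen only after the result was seen. Of 144 groups of 4 head libraries examined, 12 held a library far from the others, where chance gives about 1 in 20. In scaled FPKM, supernatant 1 stood apart for CG2909 (2.82, others 0) and CG10462 (10.7, others 3.42 to 3.53). Supernatant 2 stood apart for His3.3B (2441, others 305 to 328) and mRpL44 (27.4, others 23.1 to 23.4). Supernatant 3 did so for wb (5.58, others 0.479 to 0.551) and tws (14, others 8.88 to 9.27), and supernatant 4 for CG32773 (3.75, others 0.0204 to 0.113) and Pdsw (1041, others 797 to 824). Among pellets, replicate 2 stood apart for His3.3B (665, others 350.4 to 372), replicate 3 for tws (31.9, others 12.9 to 14.3) and replicate 4 for CG4169,Rpn12 (13240, others 436 to 716). The 10 highest genes held 27.8% of the summed FPKM of named genes in supernatant 2, and 20.8% to 21.9% in the other supernatants.

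Entries without a gene name, which no comparison used, held 64.1%, 73.5%, 35.2% and 97.2% of the summed FPKM in supernatants 1 to 4. In pellets 1 to 4 they held 85%, 22.3%, 79.3% and 94.1%. In each library most of this lay in very short entries. In supernatant 4, 3174 very short entries of 11275 without a name held 96.49% of the summed FPKM. In pellet 2, where the share was lowest, 171 of 6246 held 12.73%. FPKM is given per kilobase, so these are not shares of reads.

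For the number of head features changed, 1 of 35 splits, the real one, reached 326, and the highest other gave 19. This argues against a chance split only if the pairing is ignored. Among the 8 splits that part all 4 pairs the highest other gave 5, but 8 splits are too few to exclude chance. For the number of head lists, chance cannot be excluded: 11 of 35 splits gave at least 14 lists, and the highest other gave 19. Among the 8 splits that part all pairs, 2 gave 14. By single list, the real split had the smallest camera p of the 35 for ribosomal proteins and for translation factors, and the RNA granule p was reached in 2 splits. For ribosomal proteins another split still gave a camera p of 6.2e-24, so these p-values are not error rates here. For the other 11 lists called, 3 to 13 splits gave a p as small.

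The head features called higher in the pellet may owe part of their difference to transcript assembly: 32.6% of them had assembled entries in more pellets than supernatants, against 19.6% of those not called, and the median log2 difference was -0.246 in 398 features with such entries in 2 fewer pellets and 0.283 in 423 features with 2 more. Of features with FlyBase entries in all 8 libraries 0.98% were called higher and 1.8% lower, against 2.24% and 1.76% of the others, but their median spans of 1264 bp and 3333 bp differ too, so this does not separate assembly from span. As the whole cause, assembled entries in more pellets are argued against. Of the 172 features called higher, 107 had them in equal numbers of both fractions and 9 in more supernatants. A feature of several genes counted as assembled wherever no entry carried its exact joined name, so for such features these counts do not measure assembly. Features of 1 gene were 7878 of the 8720 tested, and a refit to them kept 285 of the 326 calls. Random lists matched on span had central 95% of medians from -0.29 to -0.046 for ribosomal proteins, whose median of -1.01 lay at percentile 0. For ion channels this range was 0.22 to 0.799, and the median of 0.98 lay at percentile 99.88. The random lists treat genes as independent. Members correlated at an estimated 0.348 for ribosomal proteins and 0.302 for ion channels, so the ranges are too narrow. Locus span as the whole cause is still argued against for ribosomal proteins, whose median lay below that range in each pair, from -1.17 to -0.852. The span relation repeated in single pairs too, so agreement between pairs alone does not separate span from another cause. The random lists were not matched on abundance, and quantile normalization gave ribosomal proteins a median of -0.41. For ion channels, where 3 of 35 splits gave a camera p as small, span stays open. Assembly differences where both fractions had assembled entries, and selective precipitation by b-isox, stay open and were not tested.

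The breadth of the S2 difference may partly reflect cell stocks that had diverged. Copy-number segments as the whole cause are argued against, since 84.6% of 2084 calls were kept in the same direction after the median of up to 50 neighbouring genes was taken off. Neighbouring genes did vary together (r = 0.159 across genes, against at most 0.0461 in 1000 shuffles within arms), so segments stay open for part of the calls. The median log2 fold change was 0.633 on chromosome 4 (32 genes) and 0.159 on X, against -0.0841 to 0.016 on the other arms. Segments much shorter than the window of neighbours are not taken off by it. Hygromycin or a separate cell stock cannot be told apart from Orb2B itself, because 0 libraries had Orb2B without hygromycin or the reverse.

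Transcripts of the background line were often higher in Orb2B replicate 2 than in replicate 1. Among 109 genes called lower by a log2 of 2 or more with at least 20 scaled RPKM in background, 96 were higher in replicate 2, while choosing genes under 1% of background in replicate 1 gave 17 of 18 and choosing them in replicate 2 gave 5 of 6. Background RNA mixed in at a single share is argued against, because among those 18 genes the share left in replicate 2 ran from 0.0673% (TotM) to 31.9% (HP6), with a 90th percentile 39 times the 10th. A different state of the culture stays open and was not tested. If the commonest ratio of low values marks a single read in each library, replicate 1 had 0.592 times the depth of replicate 2. Values near 0 would then be coarser in replicate 1.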

How the results depend on the processing

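Alternatives with FlyBase entries, features of 1 gene, joined loci, exact 0 as missing and locus span were chosen after seeing the data. Where no reason is given, the cause was not tested. The 2611 S2 genes became 1395 with a log2 change of at least 1 and 1255 (without Orb2B replicate 1) to 3334 (without background replicate 1) with a library left out, where the lone library is assumed to vary like the other group. Same-numbered S2 libraries deviated together only weakly (correlation across genes 0.05). With 2 libraries per group this is a single comparison, so it does not decide whether the S2 numbers pair. With the replicate block 3040 genes changed and the cell-division list lost its call (camera adjusted p = 0.125). S2 lists called were 0 with an estimated correlation, 6 to 8 with a library left out and 7 to 10 under the other settings.

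The 326 head features became 4566 with values as deposited, 1268 with the replicate block, which kept 320 of them, 207 with a log2 change of at least 1, and 66 to 209 with a replicate left out. Among fewer features tested, 58 changed with FlyBase entries in all 8 libraries, 276 in 6 replicates joined by locus and 180 in those features over replicates 1 to 4. Head lists called were 0 with an estimated correlation, 2 of 12 with FlyBase entries, 8 of 20 in 6 joined replicates, 7 of 20 over replicates 1 to 4, 11 with values as deposited (9 of the 14 kept), 12 with a minimum mean of 5 and 14 with each replicate left out. None of the lists called higher could be tested with FlyBase entries, where each had fewer than 5 members. Ion channels, neurotransmitter receptors and adhesion genes had 0 such members, and RNA granule genes had 1, at -0.66. The rho with span became 0.0205 with FlyBase entries. Fits without a covariate and over replicates 1 to 4 equal the one reported, and those without replicate 5 or 6 and with transcript length were not run.

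Of 41 calls among named head features, 25, 22, 19 and 21 were lost without replicate 1, 2, 3 and 4, where fewer libraries were used, and with the block 1 was lost and 14 named features passed in addition. The block changed no other call of a named head feature or head list. Calls lost under other settings numbered 6 with no filter, 5 with quantile normalization, 5 without the variance trend, 5 with a log2 change of at least 1, 4 with values as deposited beside the reversals, 3 and 1 with pseudocounts of 1 and 0.1, 1 among FlyBase entries and 1 among features of 1 gene. No named S2 gene reversed, and Hsp22, Hsp23, stv and CG4769 lost the call under some setting. With values as deposited 12 head features reversed, to log2 differences of 0.67 for His3.3B, 0.19 for mRpS22, 0.36 for mRpS35, 0.23 for mRpL44, 0.33 for mRpL40, 0.12 for eIF2B-gamma, 0.94 for CG4169,Rpn12, 0.23 for Prosalpha7, 0.15 for levy, 0.24 for ATPsyn-d, 0.34 for ATPsyn-gamma and 0.30 for Pdsw. CG4169,Rpn12 also reversed with quantile normalization (0.20) and in the joined features over replicates 1 to 4 (0.0946), and ranged from -1.05 to 0.34 with a replicate left out. His3.3B reversed in 6 joined replicates (0.27) and ranged from -0.52 to 0.18 with a replicate left out. The unknown depth leaves the counting error of low values unmeasured.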

Other observations

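Arc1 and MtnA were chosen after their values were seen. In S2 cells Arc1 was at 172 ± 56.5 RPKM in background and 1738 ± 657 RPKM in Orb2B cells (log2 fold change 3.38, SE 0.38, limma adjusted p = 0.000725). The metallothionein gene MtnA, which copper induces, was at 47958 ± 9846 RPKM in background and 54984 ± 12601 RPKM in Orb2B cells and did not pass (limma adjusted p = 0.751), in groups that both received copper.

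In heads, 35 tested features were listed at 0 in all 4 pellets and 46 in all 4 supernatants. Of the 154 features called lower, 3 were at 0 in at least 1 pellet, and of the 172 called higher, 2 were at 0 in at least 1 supernatant. These were dgt4, Cbl and CG10462, the largest named decreases, and CG2909 and CG8468, the largest named increases. With exact 0 as missing they had too few values left in 1 fraction and were not tested.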
